A study of Mus musculus with 12 samples.

How the data were processed

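Polyadenylated RNA from C2C12 mouse myoblasts was measured in 12 libraries. Cells were transfected with an siRNA against Zfp143 or with a non-targeting siRNA in growth medium with 10% fetal bovine serum. At 24 hours after transfection they were harvested uninduced or moved to medium with 1% horse serum for 5 days. Each of the 4 groups has 3 libraries, the labels name 1 batch, and the library kit was not strand-specific.

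The processed values come as a single file. Per the file headers and the processing steps the authors list, reads were trimmed with fastp 1.0.1, mapped with STAR 2.7.11b to GRCm39 and quantified per gene with Salmon. The Salmon version and the annotation release are not given in the sources used here. The deposited estimated count of each gene and library comes from that quantification, summed over transcripts by the authors. Over all gene IDs, tested or not, up to 7.26% of the values of a library are not whole numbers. The deposited score column of each library holds TPM values that the authors made from the estimated counts and the transcript lengths, and values recomputed from those columns differ by at most 0.1%. The deposited length column of each library holds the average effective transcript length in bases that the authors obtained with the counts. The 12 columns of FPKM values were not used here. In the column names of induced knockdown replicates 2 and 3 a pair of letters is transposed; these columns were taken as the libraries whose name they otherwise match.

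The table has 78810 lines, of which 535 repeat a gene ID with identical values and were dropped, leaving 78275 gene IDs. Estimated counts were rounded to whole numbers. Genes were kept with the filterByExpr function of edgeR (minimum count 10, minimum total 15), which left 15030 tested genes and 63245 untested ones; 477 gene IDs have no symbol. Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, statmod 1.5.0 and version 1.17.8 of data.table. Libraries were scaled by TMM factors. 1 model with a mean for each of the 4 groups was fitted to all 12 libraries with edgeR's robust quasi-likelihood method, which leaves 8 residual degrees of freedom. It gave 5 comparisons: knockdown in uninduced and in induced cells, induction in control and in knockdown cells, and their interaction. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and genes with an adjusted p under 0.05 are called higher or lower. Levels are CPM scaled by the TMM factors, given as mean ± SD. The SE of a log2 fold change comes from the posterior quasi-likelihood variance and the fitted counts. Principal components were taken from log2 CPM with a prior count of 2. The labels do not say whether replicate numbers pair the libraries, and the model was planned without a replicate term. After group means were removed, correlations between same-numbered libraries of different groups lay between -0.0586 and 0.149. Those between different-numbered libraries lay between -0.142 and 0.17, so no pairing was seen.

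The 30 gene lists, 856 symbols in all, were written before the data were examined, as were the groups, the comparisons, the test, the rule for naming genes and most of the alternative settings. They cover myogenic regulators, inhibitors of myogenic differentiation, sarcomere, myoblast fusion, excitation-contraction coupling and the neuromuscular junction, satellite and reserve cell markers, replication, mitosis, cell cycle inhibitors and pocket proteins, p53 targets, nuclear-encoded respiratory chain, mitochondrial ribosome, cytosolic ribosomal proteins, mitochondrially encoded genes, integrated stress response, unfolded protein response and heat shock, interferon response, extracellular matrix, YAP and TGF-beta targets, cholesterol synthesis, glycolysis, chromatin looping and ZNF143 partners, the Notch pathway, muscle atrophy and autophagy, and markers of 6 other kinds of cell. Each list was tested against all other tested genes with camera on voom values, at the preset correlation between genes of 0.01 and again with an estimated correlation. The fry test, run beside it, asks whether the genes of a list changed, with no reference to other genes. Counts adjusted over the list alone repeat the adjustment among the list's genes.

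Genes are named in the text by a fixed rule: Zfp143; a panel of Myf5, Myod1, Myog, Mef2c, Myh3, Acta1, Ckm, Mymk, Mymx, Id1, Cdkn1a, Ccnb1 and Mki67; and the 6 largest changes in each direction with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and log2 CPM ranges that do not overlap, predicted genes and pseudogenes left out. It also names from the 3 members of smallest p of each list past its test, in the direction of the list, and the most abundant member of each list of another kind of cell. A fold against a group with no counts is a bound against a floor of 3 counts per library, and with 1 to 3 summed counts the ratio of summed counts is given with its 95% counting interval. That interval reflects counting error alone.

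The alternatives were DESeq2 size factors, library size only, no filter beyond 1 count, at least 1 CPM in 3 libraries, the DESeq2 Wald test, limma-voom, only the groups of the comparison, a replicate term, an offset for transcript length, an adjusted p under 0.01, each library left out in turn, and the estimated correlation for lists. Leaving out both libraries that stand apart was added after the data were seen, as were 3 further lists in the closing section. The procedure was tested on simulated data of 15030 genes, of which 66 or 67 were given a known change of each size. Only genes above a minimum expected count were changed, and far fewer than were called in the data. The shares recovered need not hold for the data. For knockdown in uninduced cells it recovered 26.9% of 1.5-fold, 80.6% of 2-fold and 98.5% of 4-fold changes, with 5.52% false calls; in induced cells these were 31.3%, 76.1%, 97.0% and 8.11%. For the interaction it recovered 29.9% of 2-fold changes set in induced cells and 50.7% of those set in uninduced cells, so smaller differences are missed more often there. No gene coordinates were used, as the reference at hand is of another genome build.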

Results

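C2C12 is a mouse myoblast line that leaves the cell cycle and fuses into contractile myotubes when serum is withdrawn. The cells received an siRNA against Zfp143, the gene of the zinc finger transcription factor ZNF143, or a non-targeting control siRNA. They were either left uninduced or taken through 5 days of myogenic induction. Polyadenylated RNA was sequenced in 12 libraries, 3 in each of the 4 groups. The total estimated counts, in units of 1 M, were 18.6, 18.6 and 19.1 in the uninduced control libraries and 18.9, 18.1 and 18.8 in the uninduced knockdown libraries. They were 18.5, 18.3 and 18.2 in the induced control libraries and 13.5, 18.3 and 17.9 in the induced knockdown libraries. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between samples, which may be technical. The library preparation did not keep the strand, so overlapping genes on opposite strands cannot be told apart.

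Induction separated the libraries most. The first principal component of log2 CPM held 76.8% of the variance and parted uninduced from induced libraries. The second held 8.31% and parted the siRNAs within the uninduced cells. A pair of libraries stood apart from the others of their group. In uninduced control replicate 3, mitochondrially encoded genes took 6.02% of the counts, against 2.63% and 2.90% in replicates 1 and 2. Induced knockdown replicate 1 was the shallowest library, with 1.95% of its counts in mitochondrially encoded genes, against 3.44% and 3.47% in replicates 2 and 3.

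**Figure D1:**
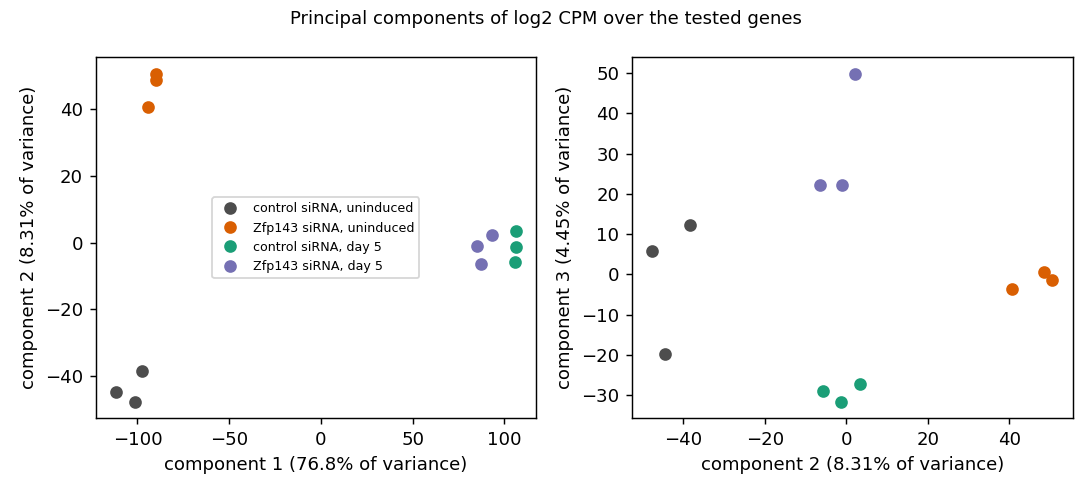
Principal components of log2 CPM over the 15030 tested genes, with 1 point per library and colours for the 4 groups; the left panel plots component 2 against component 1 and the right panel component 3 against component 2, each axis with its percent of variance. Component 1 (76.8%) parts uninduced from induced libraries, and on component 3 induced knockdown replicate 1 lies at 49.8, above the other induced knockdown libraries at 22.2.

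The siRNA lowered its target in uninduced cells. Zfp143 (ENSMUSG00000061079.16) stood at 30.3 ± 8.58 CPM (SD, n = 3) with the control siRNA and at 11.4 ± 1.10 CPM with the Zfp143 siRNA. The log2 fold change was -1.41 (95% confidence interval -1.80 to -1.02; edgeR adjusted p = 6.12e-05), which leaves 37.7% of the control level. With 1 library left out it ranged from -1.56, without uninduced control replicate 1, to -1.15, without uninduced control replicate 3. After 5 days of induction the levels were 19.4 ± 0.221 CPM and 17.1 ± 2.50 CPM (SD, n = 3), a log2 fold change of -0.18 that did not pass the test (95% confidence interval -0.57 to 0.20; adjusted p = 0.646; 88.0% of the control level). The effect on Zfp143 differed between the states, by 1.22 on the log2 scale (SE 0.257; adjusted p = 0.00358). Exact two-sided permutation tests of log2 CPM gave p = 0.1 in uninduced cells, which is the smallest value that 3 against 3 libraries allow, and p = 0.3 in induced cells. The induced comparison therefore reports cells that had received the siRNA, in which a lower Zfp143 transcript was not detected on day 5.

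**Figure D2:**
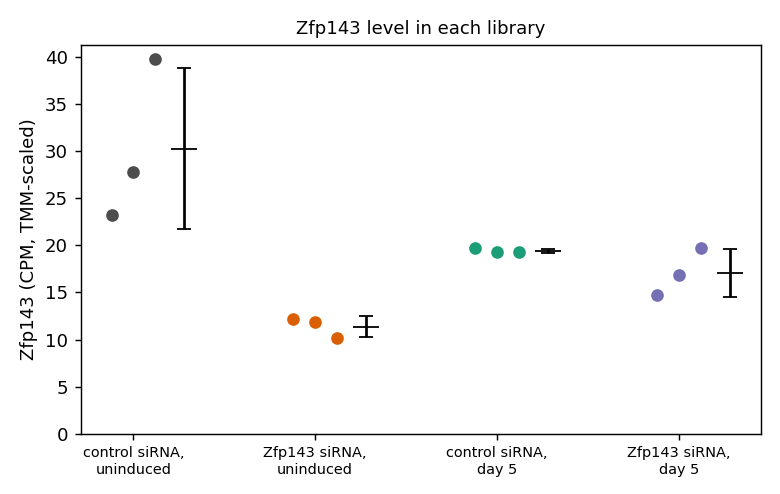
Zfp143 level in each library, in CPM scaled by the TMM factors, with 1 point per library and the mean and SD of each group of 3 as a bar beside its points. The uninduced knockdown libraries lie between 10.1 and 12.2 CPM, below the uninduced control libraries at 23.2, 27.8 and 39.8 CPM, while the induced groups overlap.

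Induction in control cells gives the reference response to differentiation. Sarcomere genes rose, with 46 of 48 measured members higher and 1 lower after 5 days (46 and 1 adjusted over the list alone). Their median log2 fold change was 9.66, or 8.06 with the 9 members that had no counts in uninduced cells set at their bound. With an estimated correlation the list was not past the test (camera adjusted p = 0.0656). Of the 30 fixed lists 5 were in this comparison: interferon response, integrated stress response, p53 targets, fibroblast and smooth muscle, and fusion. Acta1, skeletal muscle actin, went from 0.127 ± 0.113 CPM to 4206 ± 469 CPM (SD, n = 3), and Tnnt1, a troponin T of slow muscle, from 0.212 ± 0.0571 CPM to 338 ± 41.7 CPM. Myh1, a fast myosin heavy chain, had no counts in uninduced control cells and reached 974.9 ± 176 CPM, at least 5574-fold higher against a floor of 3 counts per library. Ckm, muscle creatine kinase, was at least 1736-fold higher on the same floor. Myh3, the embryonic myosin heavy chain, had 2 counts in uninduced control cells, and its ratio of summed counts was 40870 (95% counting interval 11310 to 337500). Counts are shared among near-identical paralogs such as the myosin heavy chains and the actins, so the split between these genes is less certain than their sum. All 30 genes of excitation-contraction coupling and the neuromuscular junction rose (30 adjusted over the list alone), among them Chrng, the fetal acetylcholine receptor subunit, with a log2 fold change of 8.79 (SE 0.385).

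The myogenic regulators and fusion genes followed. Of 14 measured myogenic regulators 9 rose and 1 fell (9 and 1 adjusted over the list alone). Myog, the myogenin gene, rose from 3.24 ± 0.307 CPM to 351 ± 27.9 CPM (SD, n = 3; log2 fold change 6.76, SE 0.168). Mef2c rose by 7.30 (SE 0.777) and Myod1 by 2.99 (SE 0.224), while Myf5, a marker of undifferentiated myoblasts, fell by 1.25 (SE 0.149). Of 24 fusion genes 16 rose and 2 fell (16 and 2 adjusted over the list alone). Mymk, which encodes the fusion protein myomaker, rose by 10.60 on the log2 scale (SE 0.563). Mymx, which encodes its partner myomixer, had 1 count in uninduced control cells and a ratio of summed counts of 1521 (95% counting interval 273 to 60130).

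Replication genes fell in 41 of 44 cases and 1 rose (42 and 1 adjusted over the list alone), and Mcm2, of the replicative helicase, fell by 2.42 on the log2 scale (SE 0.122). Mitosis genes were less uniform, as 28 of 42 fell and 3 rose (30 and 3 adjusted over the list alone). Ccnb1, the gene of cyclin B1, fell by 1.93 (SE 0.222), whereas Mki67, a marker of cycling cells, rose by 0.80 (SE 0.162). The gene of the cell cycle inhibitor p21, Cdkn1a, had a log2 fold change of -0.31 that did not pass the test (SE 0.129; adjusted p = 0.0507). It did pass with the transcript length offset (0.0235), the DESeq2 Wald test (0.0184) and limma-voom (0.0388), and without uninduced control replicate 3 (0.00658) or induced control replicate 2 (0.0369). Id1, an inhibitor of MyoD family proteins, fell by 0.93 (SE 0.148). Ribosomal protein genes fell in 72 of 75 cases (73 adjusted over the list alone). Mitochondrial ribosome genes fell in 57 of 78 with 1 that rose (57 and 2 adjusted over the list alone). Nuclear-encoded respiratory chain genes fell in 39 of 78 with 5 that rose (38 and 5 adjusted over the list alone). Of the targets of p53, 19 of 27 fell and 4 rose (20 and 4 adjusted over the list alone), led by Psrc1 and Mdm2, the gene of the p53 ubiquitin ligase, with log2 fold changes of -2.69 (SE 0.136) and -2.59 (SE 0.135). Genes of the integrated stress response fell in 27 of 29 cases (28 adjusted over the list alone), and Slc7a11, a cystine transporter, dropped from 143 ± 5.91 CPM to 2.76 ± 0.348 CPM (SD, n = 3).

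Interferon response genes rose without exception among the 36 measured (36 adjusted over the list alone), with a median log2 fold change of 8.62, or 8.47 with 4 members at their bound. Ifit1, an antiviral effector, went from 1.13 ± 0.139 CPM to 669.8 ± 15.8 CPM (SD, n = 3). Extracellular matrix genes rose in 31 of 37 cases and fell in 2 (31 and 2 adjusted over the list alone), and Postn, the periostin gene, rose by 8.12 (SE 0.210). Cholesterol synthesis genes rose in 19 of 25 cases (19 adjusted over the list alone, with 1 lower). Target genes of YAP and TGF-beta rose in 11 of 19 cases and fell in 4, and satellite and reserve cell markers rose in 12 of 16 and fell in 3, with the same counts adjusted over the list alone. Markers of fibroblasts and smooth muscle moved with induction too: 9 of 10 rose and 1 fell (9 and 1 adjusted over the list alone). Their most abundant member, Acta2 of smooth muscle actin, went from 10.9 ± 1.81 CPM to 2368 ± 274 CPM (SD, n = 3). Of the 15 genes written into this list, Acta2 and Cnn1 are also in the YAP and TGF-beta list, Des in the sarcomere list, Dcn and Lum in the matrix list and Rgs5 in the satellite cell list.

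Of 15030 genes tested, 9636 differed with induction in control cells, 4992 higher and 4644 lower, and 3354 of the higher and 2221 of the lower ones by more than 2-fold. With library size as the only scaling the split was 5715 higher and 3652 lower, on a median log2 fold change of all genes of 0.21 instead of 0.03. The camera test passed 19 of 30 lists, 5 of which held with an estimated correlation: interferon response (adjusted p = 4.15e-20, and 0.0352 with an estimated correlation), integrated stress response (8.23e-18 and 0.0205), p53 targets (3.42e-05 and 0.0205), fibroblast and smooth muscle (1.95e-05 and 0.0205) and fusion (0.000207 and 0.0371). Those lost with an estimated correlation were sarcomere (adjusted p = 9.03e-21, and 0.0656 with an estimated correlation), excitation-contraction coupling (3.99e-14 and 0.051), ribosomal proteins (4.04e-14 and 0.372), replication (5.05e-13 and 0.0528), matrix (2.13e-12 and 0.104) and the mitochondrial ribosome (5.66e-07 and 0.409). So were cholesterol synthesis (2.96e-05 and 0.051), mitosis (7.8e-05 and 0.255), the respiratory chain (0.00214 and 0.656), YAP and TGF-beta targets (0.0092 and 0.255), myogenic regulators (0.00946 and 0.173) and satellite cell markers (0.0198 and 0.0959). The unfolded protein response and heat shock list (13 of 24 lower and 5 higher, adjusted p = 0.0456) and the list of chromatin looping and ZNF143 partners (9 of 18 lower and 1 higher, adjusted p = 0.045) were past the test with camera's preset correlation, at adjusted p = 0.255 and 0.333 with an estimated correlation, and the counts adjusted over the list alone were the same. Both were also lost without uninduced control replicate 3, at adjusted p = 0.0733 and 0.0707, as was the respiratory chain list at 0.0581. The unfolded protein response was further lost without induced control replicate 3 (0.0582), and looping and partners without uninduced control replicate 2 (0.0689) or induced control replicate 1 (0.0636). With library size as the only scaling both were lost (0.0608 and 0.0944), and the unfolded protein response was lost with a replicate term too (0.057). Without both libraries that stand apart the adjusted p was 0.0791 for the unfolded protein response, 0.0512 for looping and partners and 0.058 for the respiratory chain. Not past the test were inhibitors of myogenic differentiation (8 of 13 higher and 4 lower; camera adjusted p = 0.401), cell cycle inhibitors and pocket proteins (8 of 11 higher and 2 lower; 0.26) and the Notch pathway (7 of 15 higher and 4 lower; 0.401). Nor were muscle atrophy and autophagy (7 of 22 higher and 11 lower; camera adjusted p = 0.18), mitochondrially encoded genes (1 of 13 lower; 0.401) and glycolysis (7 of 24 higher and 13 lower; 0.116). Adjusted over the list alone, the lower counts were 3 for cell cycle inhibitors, 12 for atrophy, 0 for mitochondrially encoded genes and 15 for glycolysis, with the other counts as given. The glycolysis list had a median log2 fold change of -0.62 and a mean of 0.19.

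Markers of further cell types did not pass the list test with induction in control cells. Their most abundant measured members in induced control cells were Spp1 of the osteoblast and chondrocyte list at 2060 CPM, Lpl of the adipocyte list at 406 CPM, Cd14 of the macrophage and leukocyte list at 15.3 CPM, Stmn2 of the epithelial and neuronal list at 7.81 CPM and Tek of the endothelial list at 3.13 CPM. The adjusted p of these lists was 0.856, 0.401, 0.928, 0.294 and 0.745.

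Knockdown in uninduced myoblasts asks what the Zfp143 siRNA changes before differentiation. Of 24 measured glycolysis genes 19 rose and none fell (21 and 1 adjusted over the list alone). The list was past the camera test at the preset correlation but not with an estimated correlation (adjusted p = 0.273). The same holds for each of the 12 fixed lists past the test in this comparison. Slc2a1, the glucose transporter GLUT1, went from 266 ± 44.2 CPM to 628 ± 24.7 CPM (SD, n = 3; log2 fold change 1.24, SE 0.145), and Pgam1, a glycolytic mutase, rose by 1.15 (SE 0.128). Mitosis genes fell in 17 of 42 cases and 1 rose (17 and 1 adjusted over the list alone). Ccnb1 fell by 0.96 (SE 0.219) and Cenpf, a kinetochore protein gene, by 1.08 (SE 0.187), while Mki67 had a log2 fold change of -0.30 that did not pass (SE 0.163; adjusted p = 0.18). Targets of p53 rose in 13 of 27 cases and fell in 4 (13 and 5 adjusted over the list alone). Cdkn1a rose from 466 ± 62.7 CPM to 1078 ± 20.1 CPM (SD, n = 3; log2 fold change 1.21, SE 0.129), and Pmaip1, the gene of the pro-apoptotic protein NOXA, rose by 1.48 (SE 0.168).

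Genes of the integrated stress response fell in 12 of 29 cases and 1 rose (14 and 1 adjusted over the list alone). Chac1, a glutathione-degrading enzyme gene, fell by 2.12 (SE 0.168) and Slc7a5, an amino acid transporter gene, by 1.37 (SE 0.157). Of the 18 measured genes of chromatin looping and ZNF143 partners 11 fell and none rose (12 adjusted over the list alone). Zfp143 itself is in this count, with the cohesin regulator genes Pds5b, which fell by 0.86 (SE 0.154), and Mau2, which fell by 0.55 (SE 0.127). Interferon response genes rose in 17 of 36 cases (19 adjusted over the list alone) from low levels: Isg15, a ubiquitin-like antiviral protein gene, went from 1.98 ± 0.515 CPM to 7.54 ± 0.975 CPM (SD, n = 3). Muscle atrophy and autophagy genes rose in 11 of 22 cases and 1 fell (11 and 1 adjusted over the list alone), and Fbxo32, the gene of the ubiquitin ligase atrogin-1, rose by 1.06 (SE 0.126). Cholesterol synthesis genes rose in 11 of 25 cases and 1 fell (12 and 1 adjusted over the list alone), and Insig1, a sterol sensor gene, rose by 1.21 (SE 0.114). Target genes of YAP and TGF-beta rose in 9 of 19 cases and fell in 3 (9 and 4 adjusted over the list alone).

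Among the myogenic regulators 2 of 14 rose and 5 fell (2 and 5 adjusted over the list alone), and the list was not past its test (adjusted p = 0.127). Myf5 dropped from 56.8 ± 10.9 CPM to 16.9 ± 2.003 CPM (SD, n = 3; log2 fold change -1.75, SE 0.151) and Myog fell by 0.86 (SE 0.210), while Myod1 stood at -0.09 (SE 0.241; adjusted p = 0.822). Id1 rose by 0.46 (SE 0.145; adjusted p = 0.0259), a call lost without uninduced control replicate 2 (adjusted p = 0.105) and without uninduced knockdown replicate 1 or 3 (0.122 and 0.0896). A number of muscle genes rose from very low levels. Of the sarcomere list 11 of 48 rose and 1 fell (10 and 1 adjusted over the list alone), and of the excitation-contraction coupling list 12 of 30 rose and 1 fell (12 and 2 adjusted over the list alone). Tnnt2, a troponin T of embryonic muscle, went from 4.62 ± 0.443 CPM to 26.9 ± 3.25 CPM and Mymk from 0.116 ± 0.109 CPM to 0.998 ± 0.0833 CPM (SD, n = 3). Acta1 was at 0.127 ± 0.113 CPM and 0.570 ± 0.485 CPM, and its call (log2 fold change 2.04, SE 0.822; adjusted p = 0.0419) was lost without uninduced control replicate 2 or 3 (adjusted p = 0.083 and 0.0945) and without uninduced knockdown replicate 3 (0.308). It was also lost with a replicate term (0.0529), with limma-voom (0.0755) and with only the groups of the comparison in the model (0.108). Mymx, Myh3, Ckm and Mef2c had means under 0.1 CPM in both groups and were not called, except that Mef2c passed without uninduced control replicate 1 (adjusted p = 0.0415).

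The largest rises among genes that meet the naming rule were those of Sprr2h, a cornified envelope gene (log2 fold change 4.49, SE 0.338), Slc5a5, the sodium iodide symporter gene (4.32), Zfp750, an epidermal transcription factor gene (4.27), Sema7a (4.23), Gpr35 (4.20) and Tigit (4.15). The largest falls by the same rule were those of Hhip, a Hedgehog-binding protein gene (-3.36, SE 0.285), Ppargc1a, the gene of the coactivator PGC-1alpha (-2.81), G0s2 (-2.58), Gfra1 (-2.51), Lama1 (-2.44) and Pard3b (-2.41). Of 15030 genes 4886 were called, 2311 higher and 2575 lower, with 1169 and 580 of them changed by more than 2-fold. Long transcripts were lower. With the tested genes in 5 equal bins of transcript length, 1176 fell and 268 rose in the longest bin (median length 5469 bases), while 141 fell and 506 rose in the shortest. No gene list was refitted with this trend removed, either in this comparison or in the interaction. How far the trend moves a list, looping and partners among them, was therefore not tested.

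The camera test passed 12 lists, among them glycolysis (adjusted p = 8.49e-08, and 0.273 with an estimated correlation), interferon response (0.000117 and 0.298), integrated stress response (0.000168 and 0.273) and mitosis (0.000179 and 0.303). The others were looping and partners (0.00341 and 0.273), atrophy and autophagy (0.00454 and 0.273), cholesterol synthesis (0.0128 and 0.273), YAP and TGF-beta targets (0.0147 and 0.298), excitation-contraction coupling (0.0148 and 0.54), p53 targets (0.0243 and 0.273), sarcomere (0.0405 and 0.715) and ribosomal proteins (3 of 75 higher; 0.0443 and 0.873). With an estimated correlation, camera passed 0 lists after adjustment and 4 at an unadjusted p under 0.05, and fry, which asks whether a list's genes move one way on balance, passed 17. Without uninduced control replicate 3, the library with the high mitochondrial share, the adjusted p was 0.107 for the sarcomere, 0.0646 for excitation-contraction coupling and 0.0577 for YAP and TGF-beta targets. The ribosomal protein call was lost without uninduced control replicate 1 or 2 (adjusted p = 0.292 and 0.961) and without uninduced knockdown replicate 1 or 3 (0.353 and 0.0614), and the sarcomere call also without uninduced control replicate 1 (0.0701), without uninduced knockdown replicate 3 (0.0579) and with library size as the only scaling (0.0564). Without both libraries that stand apart the adjusted p was 0.127 for the sarcomere and 0.0869 for excitation-contraction coupling and for YAP and TGF-beta targets, while replication (0.0212) and the respiratory chain (0.000611) passed. Not past the camera test were, with their adjusted p, fusion (8 of 24 higher and 2 lower; 0.0949), replication (9 of 44 higher and 2 lower; 0.113), matrix (12 of 37 higher and 6 lower; 0.0681) and cell cycle inhibitors (5 of 11 higher and 2 lower; 0.0864). The unfolded protein response and heat shock list (7 of 24 higher and 8 lower; camera adjusted p = 0.921) had a median of -0.16 and a mean of 0.20. Fibroblast and smooth muscle markers (3 of 10 higher and 1 lower; 0.172) had a median of 0.52, or -0.07 with 2 members at their bound. The adjusted p was 0.712 for inhibitors of myogenic differentiation, 0.848 for satellite cell markers, 0.548 for the respiratory chain, 0.744 for the mitochondrial ribosome, 0.712 for mitochondrially encoded genes and 0.229 for the Notch pathway. Without uninduced control replicate 3 the test passed replication (0.0179), the respiratory chain (0.00103) and the Notch pathway (0.0487). Matrix passed without uninduced control replicate 1 (0.0091) or 2 (0.0242) or uninduced knockdown replicate 2 (0.0411), cell cycle inhibitors without uninduced control replicate 2 (0.0447) and leukocyte markers without uninduced knockdown replicate 3 (0.0479).

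Knockdown in induced cells asks what the Zfp143 siRNA changes in the outcome of differentiation. Sarcomere genes were lower in 46 of 48 cases and higher in none (47 adjusted over the list alone), with a median log2 fold change of -1.85. Myh7, the slow myosin heavy chain gene, stood at 179 ± 32.8 CPM with the control siRNA and 18.4 ± 2.85 CPM with the Zfp143 siRNA (SD, n = 3; log2 fold change -3.29, SE 0.188). Tnnt1 fell by 2.18 (SE 0.129). Acta1 fell from 4206 ± 469 CPM to 1435 ± 255 CPM (log2 fold change -1.55, SE 0.235), and Myh3 from 1578 ± 298 CPM to 536 ± 42.7 CPM (log2 fold change -1.56, SE 0.178). Genes of excitation-contraction coupling and the neuromuscular junction fell in 25 of 30 cases (26 adjusted over the list alone), with a median of -1.24. Casq1, the calsequestrin gene of fast muscle, fell by 3.19 (SE 0.144) and Ckm by 2.53 (SE 0.169).

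Mitosis genes rose in all 42 cases (42 adjusted over the list alone), with a median log2 fold change of 1.27. Cdc20, an activator of the anaphase promoting complex, went from 19.97 ± 0.694 CPM to 61.8 ± 1.49 CPM (SD, n = 3; log2 fold change 1.63, SE 0.127). Ccnb1 rose by 1.41 (SE 0.222) and Mki67 by 1.29 (SE 0.160). Replication genes rose in 29 of 44 cases and none fell (36 adjusted over the list alone), with a median of 0.76 and Mcm5 up by 1.20 (SE 0.131). Cdkn1a fell by 0.49 (SE 0.129; adjusted p = 0.0237), a call lost with library size as the only scaling (adjusted p = 0.137) and without induced control replicate 2 (0.142) or induced knockdown replicate 2 (0.103) or 3 (0.0814). Cholesterol synthesis genes rose in 20 of 25 cases (22 adjusted over the list alone, with 1 lower), with a median of 0.83.

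Of the 14 myogenic regulators 4 fell and none rose (8 and 1 adjusted over the list alone), a list not past the test with an estimated correlation (camera adjusted p = 0.097). Mef2c fell by 3.67 (SE 0.344), Smyd1, a muscle methyltransferase gene, by 1.40 (SE 0.143), and Myog from 351 ± 27.9 CPM to 194 ± 41.5 CPM (SD, n = 3; log2 fold change -0.86, SE 0.139). Myod1 had a log2 fold change of -0.18 (SE 0.207; adjusted p = 0.698), Myf5 of -0.49 (SE 0.152; adjusted p = 0.0601) and Id1 of 0.30 (SE 0.149; adjusted p = 0.271). Myf5 passed with the transcript length offset (0.0445), with the DESeq2 Wald test (0.0305) and with only the groups of the comparison in the model (0.0418). Fusion genes fell in 6 of 24 cases and none rose (7 and 2 adjusted over the list alone), which did not pass as a list (camera adjusted p = 0.0607). The list did pass without the shallow library, induced knockdown replicate 1 (0.0256), without both libraries that stand apart (0.0249) and with library size as the only scaling (0.0483). Mymk fell by 1.19 (SE 0.150), Mymx by 1.12 (SE 0.188) and Cav3, the caveolin gene of muscle, by 2.92 (SE 0.359).

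Markers of fibroblasts and smooth muscle also fell, 6 of 10 with none higher (6 adjusted over the list alone): Acta2 fell by 0.76 (SE 0.150) and Ly6a by 1.08 (SE 0.233). The next 7 lists were past the camera test at the preset correlation but not with an estimated one: interferon response, matrix, integrated stress response, p53 targets, respiratory chain, glycolysis, and YAP and TGF-beta targets. Interferon response genes fell in 12 of 36 cases (18 adjusted over the list alone), and Rsad2, the viperin gene, fell by 2.85 (SE 0.192). Extracellular matrix genes fell in 8 of 37 cases and 1 rose (9 and 1 adjusted over the list alone), among them Postn, which went from 1108 ± 42.6 CPM to 217 ± 17.3 CPM (SD, n = 3). Genes of the integrated stress response fell in 9 of 29 cases (11 and 1 higher adjusted over the list alone), with Atf3, a stress-induced transcription factor gene, at a log2 fold change of -1.67 (SE 0.119). Targets of p53 fell in 8 of 27 and rose in 3 (8 and 3 adjusted over the list alone). The respiratory chain list held 3 falls among 78 genes (2 adjusted over the list alone), of Cox6a2, Cox8b and Cox5a. Cox6a2 and Cox8b encode muscle forms of cytochrome oxidase subunits. The call of Cox5a (adjusted p = 0.0289) was lost with library size as the only scaling (0.122), without induced control replicate 1 (0.124) or 2 (0.106) and without induced knockdown replicate 1 (0.0802) or 3 (0.0744). Glycolysis genes fell in 6 of 24 cases (6 adjusted over the list alone), among them the muscle forms Pgam2 (log2 fold change -2.37, SE 0.174) and Pfkm (-0.64, SE 0.119). YAP and TGF-beta targets fell in 6 of 19 (8 and 2 higher adjusted over the list alone). None of the 18 looping and partner genes was called (adjusted p = 0.225).

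The largest falls among genes that meet the naming rule, with its minimum of 5 CPM in the higher group, were those of Actn2, a Z-disc protein gene (-5.29, SE 0.445), Mybpc1 (-5.25) and Mybpc2 (-5.20), myosin-binding protein genes, Cd36, a fatty acid translocase gene (-4.31), Trim30d (-3.76) and Mef2c. The largest rises by the same rule were those of Itgb4, an integrin gene (2.63, SE 0.297), Prl2c2 (2.01), Eme1 (1.91), Pif1 (1.80), Kifc1 (1.77) and Troap (1.76). Trim30d and Prl2c2 have close paralogs, so their values are less certain. Of 15030 genes 1427 were called, 560 higher and 867 lower, with 227 and 460 changed by more than 2-fold; with library size as the only scaling the split was 681 higher and 631 lower. Without induced control replicate 2 the count was 906, and without both libraries that stand apart it was 2533.

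The camera test passed 14 lists, 6 of which held with an estimated correlation: sarcomere (adjusted p = 1.97e-65, and 0.00847 with an estimated correlation), mitosis (5.98e-54 and 0.00293), excitation-contraction coupling (1.67e-29 and 0.00849), replication (1.45e-28 and 0.00849), cholesterol synthesis (1.31e-19 and 0.00293) and fibroblast and smooth muscle (5.49e-05 and 0.00967). The calls lost with an estimated correlation were interferon response (adjusted p = 2.13e-10, and 0.104 with an estimated correlation), matrix (3.01e-05 and 0.399), integrated stress response (8.23e-05 and 0.132), myogenic regulators (0.000435 and 0.097), the respiratory chain (0.00297 and 0.75), glycolysis (0.0197 and 0.529), p53 targets (0.0304 and 0.116) and YAP and TGF-beta targets (0.0388 and 0.399). Not past the test were, with their camera adjusted p, inhibitors of myogenic differentiation (0.186), satellite cell markers (0.446), cell cycle inhibitors (0.448), ribosomal proteins (0.867), the mitochondrial ribosome (0.261), mitochondrially encoded genes (0.469), the unfolded protein response (0.468), the Notch pathway (0.44) and atrophy and autophagy (0.218). The mitochondrial ribosome passed without induced control replicate 3 (0.0163), and atrophy and autophagy (0.0426) and looping and partners (0.0472) without both libraries that stand apart. Of the lists past the test, 4 were also lost without a library: the respiratory chain without induced control replicate 1 (0.0997) and glycolysis without induced control replicate 1 (0.0541) or induced knockdown replicate 3 (0.078). The others were p53 targets without induced control replicate 2 (0.0671) or induced knockdown replicate 2 (0.0546), with library size as the only scaling (0.0561) and without both libraries that stand apart (0.0501), and YAP and TGF-beta targets without induced control replicate 1 (0.0638) or induced knockdown replicate 2 (0.113) or 3 (0.0595). The shallow library, induced knockdown replicate 1, is in every value of this comparison; without it the sarcomere median was -1.84 and the mitosis median 1.34.

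**Figure D3:**
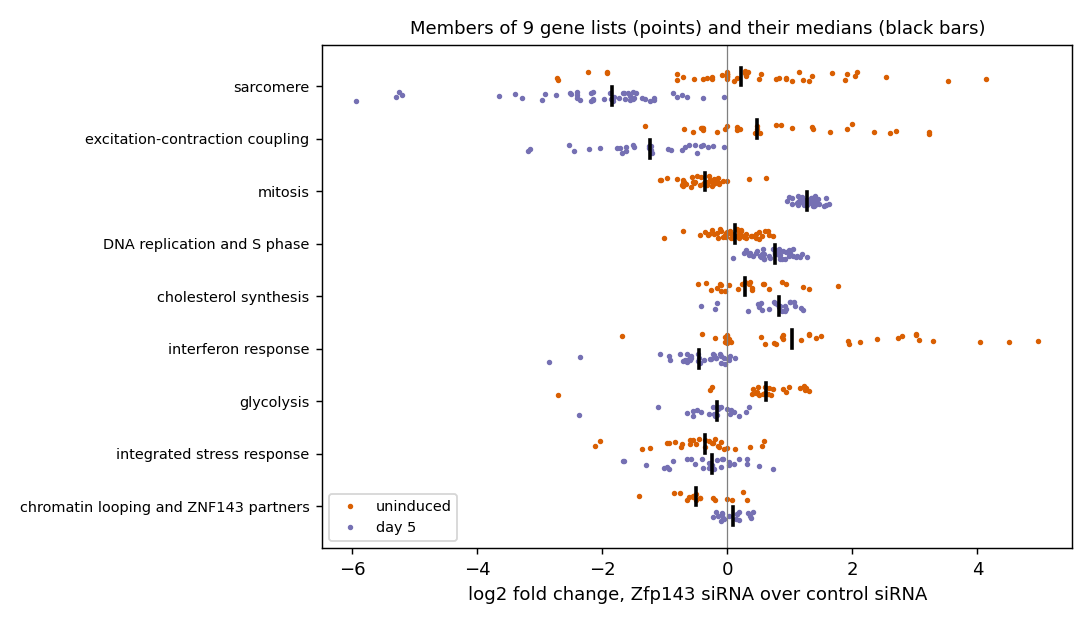
Log2 fold change of the Zfp143 siRNA over the control siRNA for the tested members of 9 gene lists, with 1 point per gene, orange for uninduced cells and purple for day 5, and a black bar at each median. At day 5 the sarcomere median lies at -1.85 and the mitosis median at 1.27, against 0.21 and -0.36 in uninduced cells.

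Induction in cells given the Zfp143 siRNA still raised the muscle program. Sarcomere genes rose in 42 of 48 cases and fell in 2 (43 and 2 adjusted over the list alone), with a median log2 fold change of 6.07, or 4.77 with 11 members at their bound, and Myog rose by 6.76 (SE 0.188). With an estimated correlation the sarcomere, mitosis and replication lists of this comparison were not past the test (camera adjusted p = 0.138, 0.157 and 0.157). Acta1 rose by 11.27 (SE 0.415) and Mymk by 6.38 (SE 0.237), and the ratio of summed counts was 899.8 for Ckm (95% counting interval 308 to 4366) and 233 for Mymx (79.3 to 1130). Mef2c had no counts in the uninduced knockdown libraries and was at least 7.31-fold higher after induction. Interferon response genes rose in 35 of 36 cases (35 adjusted over the list alone), and genes of the integrated stress response fell in 27 of 29 and rose in 1 (28 and 1 adjusted over the list alone). Mitosis genes rose in 32 of 42 cases and 1 fell (33 and 1 adjusted over the list alone). Mki67 rose from 47.0 ± 10.1 CPM to 245 ± 21.6 CPM (SD, n = 3; log2 fold change 2.38, SE 0.161), while Ccnb1 had a log2 fold change of 0.44 that did not pass (SE 0.220; adjusted p = 0.0888). Ccnb1 passed with library size as the only scaling (0.00338), with only the groups of the comparison in the model (0.0317) and without induced knockdown replicate 1 (0.0479). Replication genes fell in 29 of 44 cases and rose in 4 (29 and 4 adjusted over the list alone). Cdkn1a fell by 2.01 (SE 0.129), Id1 by 1.08 (SE 0.147), and Myf5 stood at 0.01 (SE 0.154; adjusted p = 0.963). Zfp143 rose by 0.59 (SE 0.185; adjusted p = 0.0118), a call lost without uninduced knockdown replicate 3 (adjusted p = 0.0541) or induced knockdown replicate 3 (0.0571).

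In these cells 9932 of 15030 genes were called with induction, 5406 higher and 4526 lower, of which 3364 and 2300 changed by more than 2-fold; with library size as the only scaling the split was 6597 higher and 3371 lower, on a median log2 fold change of all genes of 0.35 instead of 0.10. The camera test passed 19 lists, of which 5 held with an estimated correlation: p53 targets (22 of 27 lower and 4 higher; adjusted p = 3.04e-08, and 0.0103 with an estimated correlation), integrated stress response (6.57e-17 and 0.0182), cholesterol synthesis (23 of 25 higher and 1 lower; 1.54e-08 and 0.0188), fibroblast and smooth muscle (9 of 10 higher and 1 lower; 6.46e-05 and 0.0188) and interferon response (1.48e-18 and 0.034). Lost with an estimated correlation were, among others, the sarcomere (adjusted p = 4.06e-14, and 0.138 with an estimated correlation), ribosomal proteins (75 of 75 lower; 3.64e-17 and 0.283), excitation-contraction coupling (25 of 30 higher and 1 lower; 1.54e-08 and 0.136), mitosis (1.33e-06 and 0.157), replication (2.38e-06 and 0.157), glycolysis (5 of 24 higher and 19 lower; 3.93e-05 and 0.19) and atrophy and autophagy (5 of 22 higher and 15 lower; 0.0047 and 0.136). For these 4 lists with counts here and for those that held, the counts adjusted over the list alone were the same, except for the integrated stress response as given.

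The interaction asks whether the response to induction differs with the siRNA, which is the same as asking whether the siRNA effect differs between the states. The states also differ in the days since transfection and in the remaining Zfp143, at 37.7% of control in uninduced and 88.0% in induced cells. These differences cannot be told apart from cell state. Mitosis genes had a higher response with the Zfp143 siRNA in 41 of 42 cases (42 adjusted over the list alone), with a median difference of 1.70 on the log2 scale. Kif20a, a mitotic kinesin gene, differed by 2.21 (SE 0.172) and Ccnb1 by 2.38 (SE 0.312). The mitosis list held with an estimated correlation (camera adjusted p = 0.035), and the others of the 30 fixed lists did not in this comparison. Replication genes had a higher response in 20 of 44 cases (21 and 1 lower adjusted over the list alone). Sarcomere genes had a lower response in 26 of 48 cases (27 adjusted over the list alone), with a median of -2.17, and Tnnt2 differed by -4.18 (SE 0.212). Some sarcomere members had no counts in an uninduced group, so their differences, and with them this median, can depend on the prior count. Genes of excitation-contraction coupling had a lower response in 21 of 30 cases (22 adjusted over the list alone) and glycolysis genes in 15 of 24 (18 adjusted over the list alone). So did interferon response genes in 19 of 36 (20 adjusted over the list alone) and p53 targets in 12 of 27 with 3 higher (12 and 3 adjusted over the list alone). Cdkn1a differed by -1.70 (SE 0.183), from a rise with the siRNA in uninduced cells to a fall in induced cells. The log2 fold change of Myog was -0.86 in both states (interaction adjusted p = 1). The differences of Myod1 and Id1 did not pass, at -0.10 (SE 0.318; adjusted p = 0.865) and -0.15 (SE 0.208; adjusted p = 0.653).

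The interaction called 3375 genes, 1595 higher and 1780 lower; without both libraries that stand apart the count was 5765. The camera test passed 15 lists, of which mitosis (adjusted p = 1.92e-31) held with an estimated correlation, at 0.035. Lost with an estimated correlation were the sarcomere (adjusted p = 4.57e-17, and 0.125 with an estimated correlation), excitation-contraction coupling (1.18e-10 and 0.125), replication and glycolysis (9.83e-09 and 0.125 for each), interferon response (4.28e-08 and 0.128) and p53 targets (0.00868 and 0.125). So were matrix (3 of 37 higher and 13 lower; 0.000139 and 0.401), atrophy and autophagy (1 of 22 higher and 12 lower; 0.000614 and 0.125), looping and partners (8 of 18 higher; 0.000807 and 0.125) and YAP and TGF-beta targets (3 of 19 higher and 9 lower; 0.00207 and 0.153). The last were fibroblast and smooth muscle (1 of 10 higher and 5 lower; 0.00327 and 0.125), cholesterol synthesis (9 of 25 higher and 3 lower; 0.00784 and 0.153), the respiratory chain (3 of 78 lower; 0.0145 and 0.843) and fusion (2 of 24 higher and 5 lower; 0.0252 and 0.125). The respiratory chain was lost without uninduced control replicate 1 (0.0896) or 2 (0.235), uninduced knockdown replicate 1 (0.1), induced control replicate 1 (0.0849) or induced knockdown replicate 1 (0.0665), and fusion without uninduced control replicate 3 (0.0683). Ribosomal proteins (camera adjusted p = 0.0698) passed without uninduced control replicate 3 (8.86e-10), uninduced knockdown replicate 2 (0.0118), induced control replicate 3 (0.0133) or induced knockdown replicate 2 (0.0153), and the mitochondrial ribosome (0.644) without uninduced control replicate 3 (0.0161). Without both libraries that stand apart both lists passed (1.48e-09 and 0.0211), and ribosomal proteins passed with library size as the only scaling (0.0478). The remaining folds of the interaction are in the closing section.

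The sets of genes called by knockdown in the 2 states overlapped in 574 genes, of which 236 (41.1%) moved the same way. These comparisons share no library, and they differ in time since transfection and in remaining Zfp143 as well as in cell state. Higher in uninduced and lower in induced cells were 235 genes, against 133 from the product of the shares, and higher in both were 121, against 86.1. Lower in both were 115, against 148.5, and lower then higher were 103, against 95.9. Across the 15030 genes the log2 fold changes of the states had a Pearson correlation of -0.06 and a Spearman correlation of -0.02; genes are not independent replicates. At an adjusted p under 0.01 the genes that moved the same way numbered 83 of 240.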

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

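Tests chosen after the result was seen were those of the control library with a high mitochondrial share, hypoxia-inducible genes, the shallow library, the transcript length trend for sarcomere genes, a smaller share of differentiated cells, leukocyte genes and siRNA transfection.

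The effect of the Zfp143 siRNA differed between uninduced and induced cells, by the interaction of the model, for 3375 genes. Time since transfection and the remaining Zfp143 level also differ with the state, so their part cannot be told apart. Of 100 relabelings of the siRNA within each state, drawn from 200, 1 called as many, the real one, and the highest other called 3348. That other exchanges the siRNA names of all induced libraries, so it keeps the groups of the study whole, and the next, at 2736, leaves the uninduced names in place. Relabelling within a state removes the siRNA effect there, so this count does not test whether the effect is the same in both states, and chance is left open by it. By the naming rule the largest differences toward a higher response with the Zfp143 siRNA were those of Hhip (3.67), Ccdc40 (3.33), Sp8 (3.12), Gprin3 (2.96), Ppp2r2b (2.89) and Zfp961 (2.69), on the log2 scale. Those toward a lower response were Mybpc2 (-9.34), Ms4a4d (-8.20), Hspb7 (-7.53), Il1rl1 (-6.65), Alpk3 (-6.54) and Serping1 (-6.48). From the fixed panel Ccnb1 (2.38), Mki67 (1.59), Myf5 (1.26), Zfp143 (1.22), Cdkn1a (-1.70), Acta1 (-3.59), Mymk (-4.22) and Ckm (-5.75) differed. The folds of Ckm, Serping1, Alpk3, Hspb7, Ms4a4d and Mybpc2 depend on the prior count, since a group stands at 0. The call of Gprin3 was lost without uninduced knockdown replicate 1 (adjusted p = 0.056) or 3 (0.0828) and with limma-voom (0.0734). The call of Ckm (adjusted p = 0.033) was lost without uninduced control replicate 1 (0.0522) or 2 (0.0585) and without uninduced knockdown replicate 2 (0.162) or 3 (0.0735).

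The lists that differed between the states had these medians of the interaction: mitosis 1.70, chromatin looping and ZNF143 partners 0.53, replication 0.53, cholesterol synthesis 0.50, respiratory chain -0.17, p53 targets -0.17, fusion -0.28, YAP and TGF-beta targets -0.53, matrix -0.56, atrophy and autophagy -0.70, glycolysis -0.92, fibroblast and smooth muscle -1.07, interferon response -1.48, excitation-contraction coupling -1.72 and sarcomere -2.17. The mitosis list alone was past the threshold with an estimated correlation.

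Knockdown changed 4886 genes in uninduced cells, and a candidate technical source is the control library with a high mitochondrial share. Without it 89.4% of the calls were made again in the same direction, and after removal of a trend of each library on transcript length 77.3% were, with 2653 genes higher and 1868 lower, so neither accounts for all of the calls, though the balance of directions depends on the trend. Of 24 hypoxia-inducible genes 20 were higher, while Vegfa, Ero1a, Ddit4 and Ndrg1 had log2 fold changes between -0.03 and 0.01 and were not called. Lower oxygen or denser cultures in the knockdown wells may contribute. This cannot be told apart from an effect of the siRNA, since every knockdown library would share it.

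In induced cells sarcomere genes were lower and mitosis genes higher with the Zfp143 siRNA. Without the shallow knockdown library the sarcomere median was -1.84, and after removal of a trend of each library on transcript length it was -1.83 (median move of all genes 0.0177), while the median of each of the 5 bins of length lay between -0.05 and -0.01, so neither accounts for the pattern. If a smaller share of cells had differentiated, with all genes alike in the rest, the sarcomere genes would fall by one factor. The SD of the log2 fold changes of the 35 sarcomere genes that rose over 32-fold with induction was 1.26, against a median SE of 0.181, from -5.94 for Myl2 to -0.73 for Actn3, chosen as the extremes after their values were seen. Myl2 does not meet the naming rule, and how far genes with few counts widen this SD was not tested. How single cells differ cannot be read from these libraries, and an effect of the siRNA on genes other than Zfp143, whose own fall was not detected on day 5, stays open.

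Interferon response genes rose with induction. The 7 leukocyte genes Ptprc, Lyz2, Tyrobp, Fcer1g, C1qa, C1qb and C1qc summed to 0.576 CPM in induced control cells. The interferon list summed to 8749 CPM, which argues against leukocytes as the source of the rise. Cd14, the most abundant measured member of the macrophage and leukocyte list, is not among the 7. The list rose with a median of 6.30 in cells given the Zfp143 siRNA and of 8.62 in control cells. With no untransfected cells among the libraries, a response to the transfected RNA and to the days after it cannot be told apart from differentiation.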

How the results depend on the processing

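The setting chosen after the data were seen was leaving out both libraries that stand apart, uninduced control replicate 3 and induced knockdown replicate 1. The scalings, filters, tests, the length offset and the replicate term kept each count of genes within 1.5 times its value. At an adjusted p under 0.01 the counts were 2891 for knockdown in uninduced cells, 846 in induced cells and 1740 for the interaction, and the genes that moved the same way in both states were 83; a stricter threshold calls fewer by construction. With both apart libraries left out, knockdown in induced cells called 2533 genes and the interaction 5765, although fewer libraries were used; the cause was not tested. The median of mitochondrially encoded genes with knockdown in uninduced cells then turned to 0.27 (camera adjusted p = 0.0331), from -0.33 (adjusted p = 0.712). Without uninduced control replicate 3 alone it was 0.28 and not past the threshold (adjusted p = 0.163), and the cause of the call was not tested.

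Without 1 library the counts ranged from 3444 to 5725 for knockdown in uninduced cells, 906 (without induced control replicate 2) to 1369 in induced cells, 8816 to 9492 and 9038 to 9569 for induction in control and knockdown cells, and 2523 to 4753 for the interaction. With an estimated correlation the lists past camera's test were 0 of 12, 6 of 14, 5 of 19, 5 of 19 and 1 of 15, in the order uninduced, induced, induction in control cells, induction in knockdown cells and interaction; of the 0, 4 were past an unadjusted p under 0.05, and fry called 17. Genes named by the rule were refitted under DESeq2 size factors, library size only, the DESeq2 Wald test, limma-voom, only the groups of the comparison, the replicate term, the length offset and each library left out, not under the filters, the stricter threshold or both apart libraries left out. Where these apply, they kept their direction and side of the threshold in 60 of 67 cases, 61 of 65, 75 of 76, 74 of 76 and 65 of 69, in the same order. Apart from Zfp143 and the fixed panel, these genes were picked for large folds or small p in the same data. High shares were therefore likely in advance. Of all calls, 69.55% to 89.4% were made again in the same direction without 1 library for knockdown in uninduced cells. In induced cells these shares were 62.93% to 82.69%, and for the interaction 73.3% to 97.01%. For induction they were 90.62% to 93.79% in control and 90.21% to 92.4% in knockdown cells. Library size alone moved the median log2 fold change of all genes to 0.21 for induction in control cells and 0.35 in knockdown cells. Some muscle genes with few counts per library in uninduced cells changed their call with the setting. These were Acta1 and Mef2c for knockdown in uninduced cells and Ckm for the interaction, while Mymk kept its calls. The interaction calls of the respiratory chain genes Cox6a2 and Cox5a were also lost in several fits without 1 library. The edgeR adjusted p there was 0.0515 to 0.0649 for Cox6a2 and 0.0576 to 0.11 for Cox5a. Cox5a was lost with library size as the only scaling too (0.0889).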

Other observations

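The 3 lists of this part were written after the table of all genes was seen, so their tests were chosen after the result. Their p-values were adjusted over these 3 lists alone, and those of the fixed lists over 30. The adjusted values therefore cannot be set beside those of the fixed lists. The counts of other splits of the libraries were planned.

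In uninduced cells the Zfp143 siRNA came with higher levels of hypoxia-inducible genes, immediate early genes and targets of the oxidative stress factor NRF2. Hypoxia-inducible genes rose in 20 of 24 cases with none lower, with a median log2 fold change of 1.23 (camera adjusted p = 2.85e-17, and 0.00317 with an estimated correlation), and 6 of the 24 are also in the fixed lists. Adm, the adrenomedullin gene, rose by 3.61 and Egln3, an oxygen-sensing hydroxylase gene, by 1.70, while Vegfa stood at -0.03 (edgeR adjusted p = 0.891). Immediate early genes rose in 20 of 26 cases and 1 fell, with a median of 1.33 (camera adjusted p = 5.03e-13, and 0.0181 with an estimated correlation), among them Arc (3.95) and Fos (1.83), while Egr1 stood at 0.06. Targets of NRF2 rose in 11 of 22 cases and 1 fell, with a median of 0.42 (camera adjusted p = 6.5e-06, and 0.0181 with an estimated correlation); Hmox1, the heme oxygenase gene, went from 840.0 CPM to 2809 CPM. Before adjustment, camera with an estimated correlation gave p = 0.00106 for hypoxia-inducible genes. It gave 0.016 for immediate early genes and 0.0181 for targets of NRF2. The lowest such p among the 30 fixed lists was 0.0251, which became 0.273 after adjustment. The added lists were written after these values were seen, which can lower their unadjusted p too. Their p-values, adjusted or not, therefore cannot be ranked against those of the fixed lists. The genes named here were chosen after their values were seen.

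In induced cells immediate early genes fell in 14 of 26 cases and 1 rose (median -0.58; camera adjusted p = 2.41e-09, and 0.0493 with an estimated correlation), and targets of NRF2 rose in 9 of 22 with none lower (median 0.37; camera adjusted p = 8.3e-07, and 0.0343 with an estimated correlation). Hypoxia-inducible genes fell in 5 of 24 cases (camera adjusted p = 6.37e-05, and 0.0519 with an estimated correlation). The interaction called 20 hypoxia-inducible genes and 21 immediate early genes, with a lower response in each case. The hypoxia list had a median of -1.62 (camera adjusted p = 4.86e-18, and 0.00312 with an estimated correlation). The immediate early list had a median of -1.95 (camera adjusted p = 5.2e-19, and 0.00811 with an estimated correlation). The interaction subtracts the effect in uninduced cells, where both lists were high. Both were written after those values were seen, so a lower response was largely set by that choice. Their interaction p-values are therefore no separate support. For targets of NRF2 the interaction called 7 lower and 3 higher, and the list was not past the test (camera adjusted p = 0.147, and 0.376 with an estimated correlation).

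For the 4 comparisons between groups of 3 libraries, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split was 1 of 10 in each case. It called 4886 genes for knockdown in uninduced cells, 1427 in induced cells, 9636 for induction in control cells and 9932 in knockdown cells, and the highest of the other splits called 1, 1, 0 and 0 with edgeR. At an unadjusted p under 0.05 the highest of the other splits called 2195, 1276, 559 and 726. Each other split mixes libraries of both groups, so a group effect adds to the spread within its arms. Few calls there were therefore likely in advance, and these counts leave chance open.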
